A study of Gallus gallus with 14 samples.

How the data were processed

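Total RNA from retinas of wild type White Leghorn chickens was measured in 14 libraries, 7 from lens-wearing and 7 from control birds, made with a stranded total RNA kit and depletion of ribosomal RNA. Birds were fitted with -10 D lenses at 3 days of age and wore them for 3 days. Per the submitters' processing notes, STAR and Partek were used with the GRCg6a genome; their versions and roles, the gene annotation, the counting and its use of strand are not stated in the sources used here. Genes that overlap on opposite strands are therefore uncertain.

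The deposited table gives CPM plus an offset of 0.0001, per library, as read from the values: after the offset was taken off, 93.3% of low values in the mean library (93.0% to 93.8%) lay within 0.02 of a whole multiple of a single step, checked up to 200 reads. The columns sum to 303456 to 333244, so the listed genes hold 30.3% to 33.3% of the totals that the authors divided by. The step worth 1 read implies totals of 30.8 to 41.4 M reads per library. A floor of 3 counts corresponds to 0.0724 to 0.0973 CPM. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Libraries of a group differed from each other by 5.62 to 42.3 times the counting error in 42 pairs (chi-square per degree of freedom, median 13.5), so none were copies. Symbols were matched to a table of genes on the GRCg7b assembly, used here to name chromosomes only: 15419 of 18631 symbols matched. Each sequence of the deposited table took the chromosome of most of its matched symbols, with 879 genes on chromosome Z and 48 on W.

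Each library kept the deposited scaling. Values were analysed as log2(CPM + 1). A gene was tested when at least 7 libraries reached 0.5 CPM computed on the column sum, which is 0.152 to 0.167 CPM, and 14259 genes passed. Groups followed the treatment label. Lens and control were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No covariate was used, and no pairing, since no number in the sample codes occurs in both groups. Principal components were compared by exact permutation over all assignments of 7 of the 14 libraries. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

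The tests, the filter, the naming rule and 43 gene lists were fixed before the data were examined. Lists covered retinal cell types, signalling, metabolism and stress, and 42 had at least 5 tested members; the list of mitochondrially encoded genes had 0. Lists were tested with camera (preset correlation 0.01, and an estimated correlation beside it) and with fry, adjusted over the lists. The text describes 15 lists, and 79 genes follow the naming rule, 1 of which is not reported here. The rule takes genes with a symbol and at least 2 CPM, computed on the column sum, in the higher group: the 10 largest rises and falls among genes that passed, the 10 smallest p-values, every candidate gene of eye growth, and up to 4 members with the smallest p-value from each list described. Members that passed adjusted over the list alone are also named where they account for the count of a list.

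The procedure was tested on simulated data with 14259 genes, of which 200 were changed. At the smallest fold simulated, below the 1.5-fold step, 21 of 67 changed genes were recovered (31.3%). At 1.5-fold 38 of 67 changed genes were recovered (56.7%), and at 2-fold 52 of 66 (78.8%), with 4 false calls among 115 (3.48%). Of the simulated lists shifted by 0.15 on the log2 scale, 2 of 2 were recovered and 0 of the others were called. Simulated genes were drawn independently, whereas members of the real lists were correlated (estimated correlation 0.315 for phototransduction). These rates of false calls therefore do not carry over to the real libraries, where another split called up to 15 lists by camera.

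Alternatives fixed in advance were other pseudocounts (0.1 and 5), other filters, median ratio and quantile scaling, robust and weighted variance models, the last letter of the sample code as a covariate, an exact Wilcoxon test, and leaving out each library in turn. Added after seeing the data were W-linked RNA as a covariate, the 9 libraries without it, removal of genes on Z and W, rescaling to the same sum over the listed genes, and voom on recovered reads. W-linked RNA was called where the mean log2 level of the 2 tested W genes lay above 2, a call that rests on HINTW. The comparison was also repeated over 100 of the 1716 splits of the 14 libraries into groups of 7.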

Results

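Retinas of White Leghorn chickens were profiled by RNA sequencing after 3 days of wearing a -10 D lens, which defocuses the image behind the retina and drives the eye to elongate, and in control retinas. The groups held 7 lens libraries and 7 control libraries, all from wild type birds whose age label reads postnatal day 3. The table listed 18631 genes, and each column summed to 303456 to 333244 CPM. The control columns summed to 318340 ± 9117 (SD, n = 7) and the lens columns to 312080 ± 7106 (SD, n = 7). The step worth 1 read implied totals of 30.8 to 41.4 M reads per library, with means of 37.4 ± 3.06 M reads in controls and 37.5 ± 3.80 M reads in lens libraries (SD, n = 7 each). The listed genes held 9.68 to 13.8 M of these reads. A count of 0 therefore allowed a level of up to 0.0724 to 0.0973 CPM, depending on the library, for counting error only. The labels do not say in words that the samples came from separate animals, so each p-value measures the spread between these samples. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes with low levels. Start and end positions are those of the deposited table, and the submitters' processing notes name GRCg6a. Chromosome names follow the GRCg7b assembly.

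The comparison of lens with control retinas asks which retinal genes change while an eye compensates for imposed defocus. Most of the genes that passed the test were lower in the lens retinas. SGK1, a kinase induced by steroid hormones, fell from 42.3 ± 3.10 to 32.1 ± 3.16 CPM (SD, n = 7 each; log2 fold change -0.39, SE 0.07, adjusted p = 0.034). CAMK1D, a calcium and calmodulin-dependent kinase, fell from 76.3 ± 3.85 to 57.4 ± 7.81 CPM, and RCAN2, a regulator of the phosphatase calcineurin, fell from 52.9 ± 1.95 to 39.6 ± 5.45 CPM (log2 fold changes -0.41 and -0.42, adjusted p = 0.0413 and 0.0412). RBP4, which encodes a carrier of retinol and lies on chromosome Z, showed the only change past 1.5-fold on the log2(CPM + 1) scale, from 131.2 ± 30.5 to 73.0 ± 16.7 CPM (SD, n = 7 each; log2 fold change -0.84, SE 0.15, adjusted p = 0.0413). CEP192, a centrosome protein, was the 1 gene that rose, from 22.99 ± 1.40 to 28.2 ± 1.32 CPM (SD, n = 7 each; log2 fold change 0.28, SE 0.05, adjusted p = 0.0413).

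The other genes that fell were SHC4, MAP3K13, NPTX2, NCOA2 and a pair of transcripts known only by number. SHC4, an adaptor of receptor tyrosine kinases, went from 11.5 ± 1.09 to 8.18 ± 0.674 CPM (log2 fold change -0.45, adjusted p = 0.034). MAP3K13, a kinase of the JNK pathway, went from 73.7 ± 3.65 to 58.2 ± 5.30 CPM (log2 fold change -0.34, adjusted p = 0.034). NPTX2, a secreted synaptic pentraxin, went from 42.4 ± 2.75 to 34.2 ± 2.33 CPM (log2 fold change -0.30, adjusted p = 0.0413). NCOA2, a coactivator of nuclear receptors, went from 72.4 ± 6.36 to 55.1 ± 5.97 CPM (log2 fold change -0.39, adjusted p = 0.0413). LOC107053759, annotated as a long noncoding RNA, went from 1.28 ± 0.168 to 0.582 ± 0.172 CPM (log2 fold change -0.53, adjusted p = 0.0332); its mean fell by 54.6%, a larger share than that of RBP4, which fell by 44.4%. LOC112532219 went from 19.3 ± 1.65 to 13.1 ± 2.06 CPM (log2 fold change -0.54, adjusted p = 0.034). Each error is an SD over 7 libraries, and these last 2 transcripts fall outside the naming rule, so they were chosen after their values were seen.

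The 11 genes lie on several chromosomes. SGK1 spans 56205660 to 56278753, RCAN2 109708248 to 109785674 and LOC112532219 43232166 to 43247979, all on chromosome 3. NCOA2 spans 116501067 to 116692947 and CEP192 96924624 to 96981993, both on chromosome 2. CAMK1D spans 6924139 to 7144553 on chromosome 1, LOC107053759 32631226 to 32644723 on chromosome 6 and MAP3K13 3754982 to 3820473 on chromosome 9. SHC4 spans 10820873 to 10847604 on chromosome 10, NPTX2 1629146 to 1639636 on chromosome 14 and RBP4 53612243 to 53617574 on chromosome Z.

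**Figure D1:**
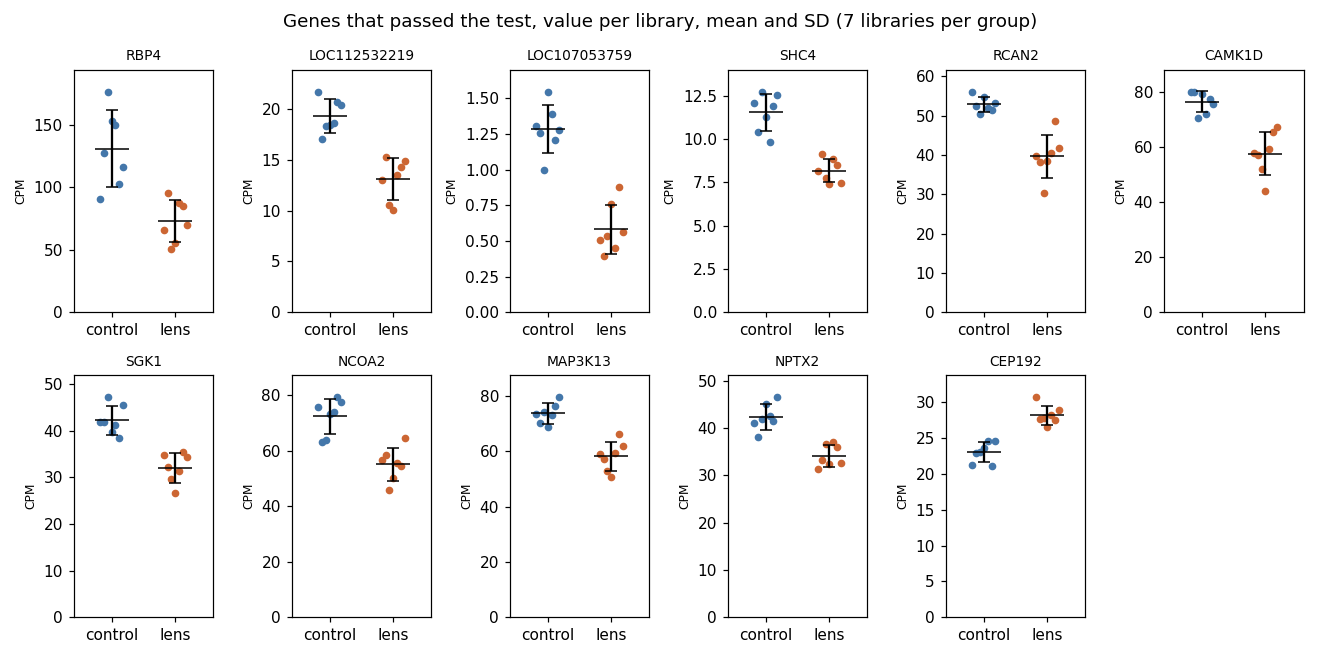
Values in CPM (vertical axes, starting at 0) of the 11 genes that passed the test, 1 panel per gene, with each point a library, and the bar and whiskers the mean and SD of 7 libraries. The groups do not overlap for 9 of the 11 genes, the exceptions being RBP4 and NCOA2.

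Of 14259 genes tested with limma, 11 changed at an adjusted p under 0.05, 1 higher and 10 lower, and 1 of them passed 1.5-fold on the log2(CPM + 1) scale (2 with a pseudocount of 0.1). The next gene was TSC22D1, with a log2 fold change of -0.35 and an adjusted p of 0.0509. At an unadjusted p under 0.05 there were 1930 genes, 432 higher and 1498 lower (77.6% lower). About 713 would be reached by chance on average, but genes are correlated, so single splits can lie far from that. Of 100 splits, the real one included, 3 gave at least 1930, and the highest other split gave 3573. The lower share was 59.8% after median ratio rescaling, 64.0% after rescaling to the same sum over the listed genes and 52.8% after quantile normalization. Among the 11 genes, 9 had groups that did not overlap, and among all genes tested 38 did (0.266%), where chance gives 0.0583% on average. The number of genes without overlap was not counted in other splits. The count of 11 genes became 0 without control replicate 1, 4, 6 or 7 or lens replicate 1 or 5. It became 1 without control replicate 3 or lens replicate 4, and 3 without lens replicate 3. It was 4 without lens replicate 2 and 18 without control replicate 5. All 11 genes kept their direction in each case, which was fixed in advance for the 9 whose groups did not overlap. The 1 gene past 1.5-fold became 0 without any 1 of control replicates 1, 3, 4, 5, 6 and 7 and lens replicates 1, 4 and 5. It became 2 without control replicate 2 and 4 without lens replicate 7. The count of 11 was 0 after quantile normalization, without the filter on low values and with an exact Wilcoxon test (1866, 2137 and 1442 genes at an unadjusted p under 0.05). Groups that do not overlap give the smallest possible Wilcoxon p. With 38 such genes its lowest adjusted p was 0.219, so even they could not pass.

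The groups also differed in W-linked RNA, which in birds is carried by females. HINTW, a W-linked gene, stood at 116.8 to 145.04 CPM in 5 libraries and at 0.0244 to 0.549 CPM in the other 9. The 5 were control replicates 2, 3, 4 and 7 and lens replicate 4, so W-linked RNA was present in 4 of 7 control and 1 of 7 lens libraries (Fisher's exact test, two-sided, p = 0.266). Z-linked genes were higher in the lens group: the median log2 fold change was 0.17 over 665 Z-linked genes and -0.04 over 13292 autosomal genes. Of the 432 genes that were higher at an unadjusted p under 0.05, 172 (39.8%) lie on chromosome Z. The difference between the medians, 0.21, was 0.03 with W-linked RNA as a covariate and 0.01 among the 9 libraries without it. RBP4 was the 1 gene of the 11 on chromosome Z.

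With W-linked RNA as a covariate, an alternative chosen after the data were seen, 19 genes changed, 3 higher and 16 lower, and 8 of them were among the 11. RBP4, CEP192 and NPTX2 no longer passed (adjusted p = 0.0746, 0.0602 and 0.0641), with log2 fold changes of -0.84 (SE 0.15) against -0.80 (SE 0.17) with the covariate for RBP4, 0.28 (SE 0.05) against 0.29 (SE 0.06) for CEP192, and -0.30 (SE 0.05) against -0.30 (SE 0.06) for NPTX2. Among the 9 libraries without W-linked RNA RBP4 stood at -0.59 (adjusted p = 0.396), CEP192 at 0.34 and NPTX2 at -0.27. The genes added, named after their values were seen, included GUCA1A, a calcium sensor of photoreceptors (log2 fold change -0.57, adjusted p = 0.00843), GCG, the glucagon precursor (-0.61, adjusted p = 0.037), and IMPG1 and IMPG2, proteoglycans of the matrix around photoreceptors (-0.35 and -0.43). The clock gene ARNTL2 also passed, with a log2 fold change of 0.45 and an adjusted p of 0.0449. Among the 9 libraries without W-linked RNA, 3 control and 6 lens, 2 genes passed, both lower and neither among the 11. These were DIO2, the deiodinase that activates thyroid hormone (log2 fold change -0.84, adjusted p = 0.00143), and the histone gene HIST1H2B7 (-0.87, adjusted p = 0.0415), both named after their values were seen. All 11 genes kept their direction in both alternatives. Among the 9 libraries that was fixed in advance for the genes whose groups did not overlap.

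**Figure D2:**
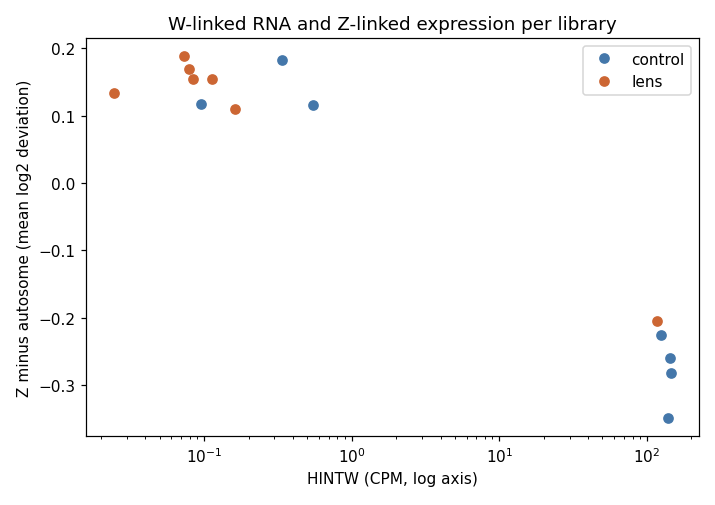
HINTW in CPM (horizontal, log axis) against the mean log2 deviation of Z-linked genes minus that of autosomal genes (vertical) in each of the 14 libraries, coloured by group. The 5 libraries with HINTW at 116.8 to 145.04 CPM, 4 control and 1 lens, lie below 0 and the other 9 lie above 0.

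The first principal component carried 26.8% of the variance and placed the lens libraries at 6.95 ± 9.86 and the controls at -6.95 ± 12.2 (SD, n = 7 each). An exact permutation test over all assignments of 7 of the 14 libraries, two-sided, gave p = 0.0373, or 0.0647 after adjustment over 3 components, so the difference did not pass; with a pseudocount of 5 it did (adjusted p = 0.0498). The groups were also mixed: control replicate 5 lay at 13.0, among the lens libraries, and lens replicate 6 at -9.87, among the controls, while control replicate 2 lay farthest out at -28.0. The second component (14.2%) did not separate the groups (exact permutation p = 0.574) but separated libraries by W-linked RNA (exact permutation p = 0.0005). The third (9.57%) gave an exact permutation p of 0.0431 for the groups, or 0.0647 after adjustment.

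**Figure D3:**
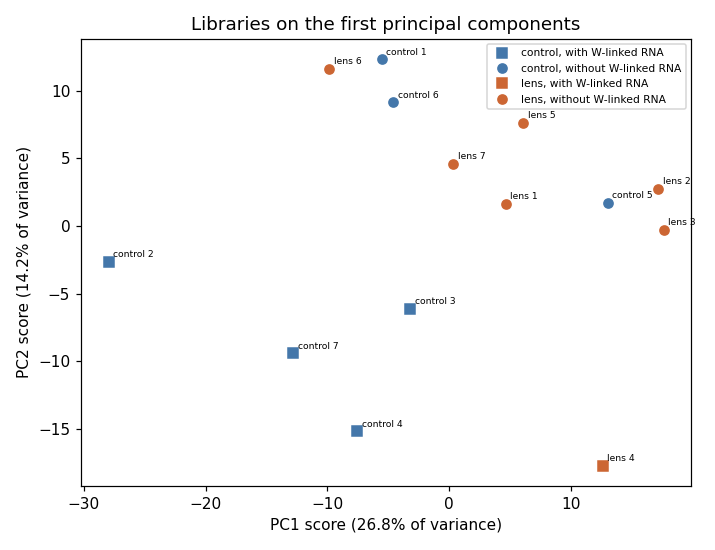
Scores of the 14 libraries on the first principal component (horizontal, 26.8% of the variance) and the second (vertical, 14.2%), coloured by group, with squares for libraries with W-linked RNA. Control replicate 5 at 13.0 and lens replicate 6 at -9.87 lie on the side of the other group.

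A list of 24 genes discussed in the eye growth field was fixed before the data were examined, and GCG, PENK, UTS2B, DRD4 and EGR1 were lower in the lens retinas. GCG, the glucagon precursor, went from 16.5 ± 2.32 to 11.2 ± 2.17 CPM (SD, n = 7 each; log2 fold change -0.53, SE 0.11, adjusted p = 0.0693 over all genes and 0.0019 adjusted over the list alone). EGR1, the gene of ZENK, a transcription factor of amacrine cells that follows the sign of defocus, went from 9.51 ± 4.52 to 4.21 ± 2.03 CPM (log2 fold change -0.96, SE 0.30). PENK, the enkephalin precursor, went from 19.1 ± 2.59 to 15.4 ± 0.737 CPM, and UTS2B, a urotensin-related peptide, from 0.950 ± 0.362 to 0.514 ± 0.183 CPM (log2 fold changes -0.28 and -0.35). DRD4, a dopamine receptor, went from 29.7 ± 3.03 to 22.99 ± 4.91 CPM (log2 fold change -0.38).

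Of the 20 candidate genes tested, 5 fell adjusted over the list alone: GCG, PENK (0.0144), DRD4, UTS2B and EGR1 (0.0198 each). With the exact Wilcoxon test 1 candidate passed by that adjustment. Over all genes tested with limma 0 candidates passed, with 6 at an unadjusted p under 0.05. The sixth was ALDH1A1, a Z-linked enzyme of retinoic acid synthesis, with a log2 fold change of 0.38 and 0.17 with the W-linked RNA covariate. Genes with values that did not pass were ALDH1A2 (0.22), NOS1 (-0.24), FOS (-0.26), ADCYAP1 (-0.21), VIP (-0.17), DRD2 (-0.15), TGFB2 (-0.11), TH (-0.10), BMP2 (-0.10), ALDH1A3 (-0.10), IGF1 (0.05) and OPN4 (-0.04), each given as a log2 fold change. GJD2 and NOG stood at -0.02 each, and the sign of GJD2 turned after median ratio rescaling, rescaling to the same sum and quantile normalization, and that of NOG after quantile normalization. BMP4, SST and NPPC were below the filter on low values, and INS was not listed in the table. Fry, unlike camera, does not set a list against other genes, and the median log2 fold change of all genes was -0.04. The list as a set did not pass camera (adjusted p = 0.0599) but passed fry (adjusted p = 0.0291), with lower values on balance. It passed camera with the W-linked RNA covariate (0.0116), among the 9 libraries without W-linked RNA (0.0273), after median ratio rescaling (0.0464), and without control replicate 2 (0.0223) or 4 (0.0331) or lens replicate 5 (0.0397) or 6 (0.0344), while its fry call was lost with that covariate (0.063). With all libraries camera gave adjusted p = 0.557 with an estimated correlation, which was not computed in those alternatives. Among the 9 libraries 6 candidates passed adjusted over the list alone: PENK did not (0.112), while FOS (log2 fold change -0.70, adjusted p = 0.00284) and ALDH1A2 (0.41, adjusted p = 0.042) did. The values of NOS1 (-0.06) and DRD2 (-0.02) lay nearer 0 in those libraries, and those of ADCYAP1, ALDH1A3, OPN4, GJD2 and NOG turned sign. Without lens replicate 3, 1 candidate passed over all genes, and without control replicate 7 EGR1 no longer passed adjusted over the list alone (adjusted p = 0.0537). ALDH1A1 passed adjusted over the list alone without control replicate 1, 5 or 6 (0.0441, 0.0429 and 0.0446) or lens replicate 4 (0.012), as did NOS1 and VIP without lens replicate 6 (0.0377 each).

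**Figure D4:**
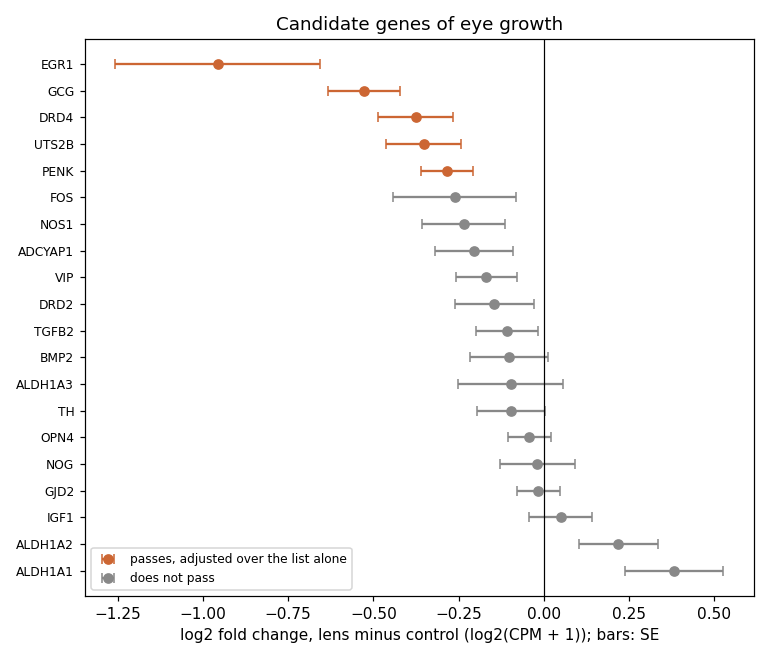
Log2 fold change, lens minus control, with its SE, of the 20 candidate genes tested, with colour for the genes that pass adjusted over the list alone. The 5 coloured genes all lie below 0, from -0.96 for EGR1 to -0.28 for PENK.

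Across 42 tested gene lists fixed before the data were examined, the lists of immediate early genes, glycolysis and hypoxia, histones, Müller glia, stress proteins and glutamate transmission were lower in the lens retinas, relative to other genes. The lists of ribosomal proteins, of cholesterol and fatty acid synthesis and of oxidative phosphorylation were higher relative to other genes. None of these lists passed fry (adjusted p = 0.242, 0.389 and 0.841). By camera with a preset correlation of 0.01, 9 lists passed, 3 higher and 6 lower. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.557, and 1 list had an unadjusted p under 0.05 by that test. By fry, which asks whether the members of a list move on balance one way, 9 lists passed, all lower. In its test for change in either direction 24 passed. Fry does not set a list against other genes, and it was not run on rescaled values. The lower values of all genes with the deposited scaling (median log2 fold change -0.04) may therefore add to these calls. With the W-linked RNA covariate 13 lists passed camera and 0 passed fry, the lowest adjusted p of fry being 0.063. Among the 9 libraries without W-linked RNA 17 lists passed camera.

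Immediate early genes, which neurons switch on with activity, were lower: 4 of 27 members fell adjusted over the list alone and 1, NPTX2, over all genes. DUSP5, a phosphatase that acts on ERK (-0.52), MAFF (-0.35) and EGR1 (-0.96) were the others that fell. With the W-linked RNA covariate 8 fell adjusted over the list alone, and among the 9 libraries without W-linked RNA 7 passed. The median log2 fold change was -0.16 (camera adjusted p = 0.000522, and adjusted p = 0.557 with an estimated correlation). Of the glycolysis and hypoxia genes, 7 of 35 fell adjusted over the list alone and 0 of them over all genes (limma, 15 at an unadjusted p under 0.05). They included HK2, a hexokinase (-0.54), SLC2A1, the glucose transporter (-0.45), VEGFA, a vascular growth factor (-0.29), and PGK1 (-0.20). HK2 and SLC2A1 alone of these 7 fell, adjusted over the list alone, with the W-linked RNA covariate (2 genes). Among the 9 libraries without W-linked RNA 0 passed by limma (5 at an unadjusted p under 0.05). There HK2 stood at -0.50, SLC2A1 at -0.40, VEGFA at -0.23 and PGK1 at -0.14. The median of that list was -0.14 (camera adjusted p = 0.00286, and adjusted p = 0.557 with an estimated correlation). Of the unfolded protein and heat shock genes, HSPA5, a chaperone of the endoplasmic reticulum (-0.44), and ATF4, a stress transcription factor (-0.27), fell adjusted over the list alone, 2 of 34, and 0 over all genes (limma, 6 at an unadjusted p under 0.05). BAG3 (-0.44) and PDIA6 (-0.22) did not pass. In the fit with the W-linked RNA covariate 1 gene fell adjusted over the list alone, while HSPA5 stood at -0.53 and ATF4 at -0.27. The median was -0.11 (camera adjusted p = 0.0247, and adjusted p = 0.557 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.0535), 5 (0.220) or 7 (0.106) or lens replicate 5 (0.0585) or 6 (0.113).

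Histone genes were lower throughout: all 42 tested members had a negative log2 fold change with the deposited scaling. Of these, 10 fell adjusted over the list alone and 0 over all genes (limma, 17 at an unadjusted p under 0.05). HIST1H111L (-0.63), HIST1H111R (-0.60), HIST1H101 (-0.55) and HIST1H103 (-0.49) had the smallest p-values. The median was -0.22 (camera adjusted p = 1.1e-06, and adjusted p = 0.557 with an estimated correlation). Ribosomal protein genes were higher by camera, with RPLP2 (0.26) the 1 of 73 that rose adjusted over the list alone, 0 over all genes (limma, 12 at an unadjusted p under 0.05) and a median of 0.06 (adjusted p = 3.5e-07, and adjusted p = 0.557 with an estimated correlation). In the fit with the W-linked RNA covariate, and among the 9 libraries without W-linked RNA, 0 ribosomal protein genes passed adjusted over the list alone by limma (11 at an unadjusted p under 0.05 in each), although RPLP2 stood at 0.26 in both. RPS6, on chromosome Z (0.54, but 0.22 with the covariate and 0.21 among the 9 libraries), and RPL27A (0.31) did not pass. Histone genes have many near-identical copies. How reads shared between similar sequences were counted is not stated, so the values of single histone genes in particular are uncertain.

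Of 33 tested genes of cholesterol and fatty acid synthesis, 4 rose adjusted over the list alone and 0 over all genes (limma, 10 at an unadjusted p under 0.05). They included HMGCS1, an enzyme of the mevalonate pathway (0.46), and STARD4, a sterol carrier (0.63), both on chromosome Z, and IDI1 (0.25), which is not. STARD4 stood at 0.31, HMGCS1 at 0.43 and IDI1 at 0.26 with the W-linked RNA covariate, and STARD4 stood at 0.40 among the 9 libraries without W-linked RNA. The median was 0.05 (camera adjusted p = 0.000329, and adjusted p = 0.557 with an estimated correlation). With the W-linked RNA covariate 0 of them passed adjusted over the list alone by limma (12 at an unadjusted p under 0.05), whereas 10 did among the 9 libraries without W-linked RNA. Nuclear genes of oxidative phosphorylation had a median of 0.02, with 0 of 72 passing either way (limma, 8 at an unadjusted p under 0.05). ATP5I (0.59) and COX7C (0.49), both on chromosome Z, UQCRB (0.17) and ATP5SL (-0.24) had the smallest p-values. ATP5I stood at 0.26 with the covariate and 0.25 among the 9 libraries, and COX7C at 0.10 in both. The camera call of that list (adjusted p = 0.0151, and adjusted p = 0.69 with an estimated correlation) was lost with the W-linked RNA covariate (0.341), and without control replicate 4 (0.0575) or 7 (0.106) or lens replicate 6 (0.369).

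Markers of Müller glia, the supporting cells of the retina, were lower as a set, with 21 of 22 below 0 and a median of -0.13, although 0 passed singly by limma adjusted over the list alone or over all genes (5 at an unadjusted p under 0.05). CYP1B1 (-0.53), NOTCH1 (-0.24), CA2, a carbonic anhydrase (-0.15), and ZEB2 (-0.15) had the smallest p-values. Camera gave an adjusted p of 0.0151, and adjusted p = 0.557 with an estimated correlation, and the call was lost without control replicate 5 (0.0535). Low medians were not particular to Müller glia: -0.13 for ganglion cells, phototransduction and photoreceptor structure, and -0.10 for amacrine cells. None of those lists passed camera (adjusted p = 0.292, 0.208, 0.389 and 0.164). The medians of bipolar (-0.03) and horizontal cells (-0.05) lay near that of all genes (-0.04). Genes of glutamate transmission had a median of -0.09, and 0 of 32 passed adjusted over the list alone or over all genes by limma (7 at an unadjusted p under 0.05). The receptors GRIN2C (-0.41), GRM4 (-0.32), GRIK3 (-0.30) and GRM5 (-0.22) had the smallest p-values, with GRIN2C at -0.26 and GRIK3 at -0.17 among the 9 libraries without W-linked RNA. Their camera call (adjusted p = 0.0282, and adjusted p = 0.557 with an estimated correlation) was lost after median ratio rescaling (0.0871) or rescaling to the same sum (0.0683), with the W-linked RNA covariate (0.122), and without control replicate 1 (0.0503) or 7 (0.111) or lens replicate 2 (0.0501) or 6 (0.144).

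**Figure D5:**
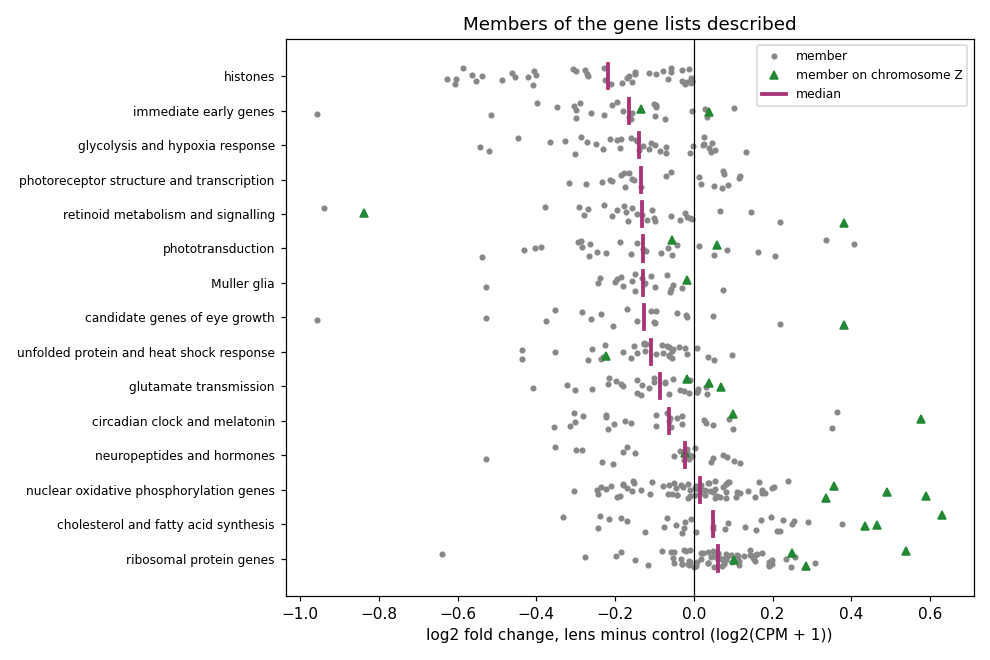
Log2 fold change, lens minus control (horizontal), of each tested member of the 15 gene lists described, with triangles for members on chromosome Z and a bar at the median of each list. The medians run from -0.22 for histones to 0.06 for ribosomal protein genes.

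Photoreceptor genes were lower in part. Of 29 phototransduction genes, 6 fell adjusted over the list alone and 0 over all genes (limma, 11 at an unadjusted p under 0.05): ARR3, the cone arrestin (-0.54), GUCA1A (-0.43), OPN1MSW, a cone opsin (-0.39), SAG, the rod arrestin (-0.29), PDE6H, a cone phosphodiesterase subunit (-0.26), and RGS9BP (-0.19). PDE6G (0.41) and SLC24A1 (0.33) were above 0 and did not pass. The list had a median of -0.13 and did not pass camera (adjusted p = 0.208, and 0.737 with an estimated correlation). It passed fry for change in either direction (0.0153). With the W-linked RNA covariate the list passed camera (0.0102, at the preset correlation only) and 4 of its genes fell adjusted over the list alone. By that adjustment 3 passed among the 9 libraries without W-linked RNA. In those 9 libraries ARR3 stood at -0.31, SAG at -0.19, OPN1MSW at -0.14 and SLC24A1 at 0.60. Of 23 genes of photoreceptor structure and transcription, IMPG1 (-0.28), IMPG2 (-0.32) and THRB, a thyroid hormone receptor (-0.16), fell adjusted over the list alone and 0 over all genes (limma, 6 at an unadjusted p under 0.05), while OTX2 (-0.21) did not pass. Its camera adjusted p was 0.389, and 6 of its genes fell adjusted over the list alone with the W-linked RNA covariate. Of 29 genes of retinoid metabolism, RBP4 alone fell, by either adjustment. RGR, an opsin of Müller glia and pigment epithelium, had a log2 fold change of -0.94 and BCO2 of -0.12, neither passing. The list had a median of -0.13 and a camera adjusted p of 0.157 (0.69 with an estimated correlation). With the W-linked RNA covariate camera gave an adjusted p of 0.0124, at the preset correlation only. Among the 9 libraries without W-linked RNA 0 retinoid genes passed adjusted over the list alone by limma (6 at an unadjusted p under 0.05).

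Clock genes moved in both directions. NFIL3, a repressor of clock output on chromosome Z (0.58), ARNTL2, a partner of CLOCK (0.35), and TPH1, an enzyme of serotonin and melatonin synthesis (0.36), rose adjusted over the list alone. PER2 (-0.28), CRY2 (-0.20), BHLHE40 (-0.35), BHLHE41 (-0.31), CSNK1E (-0.30) and OPN4-1, a melanopsin (-0.22), fell by the same adjustment. Thus 9 of 29 members passed adjusted over the list alone and 0 over all genes (limma, 11 at an unadjusted p under 0.05). The list median was -0.06 and camera did not pass (adjusted p = 0.422), whereas the fry test for change in either direction gave an adjusted p of 6.98e-06. With the W-linked RNA covariate 3 rose and 4 fell adjusted over the list alone. Among 24 neuropeptides and hormones, GCG, PENK, UTS2B and SCG2, a granin (-0.30), fell adjusted over the list alone (2 members passed among the 9 libraries without W-linked RNA) and 0 over all genes (limma, 6 at an unadjusted p under 0.05), with a list median of -0.02, a camera adjusted p of 0.282 and a fry adjusted p of 0.000357 for change in either direction.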

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

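The tests of W-linked RNA, of photoreceptor share, of exchanged labels and of splits with the same imbalance of W-linked RNA were chosen only after the results were seen. Those of time of day, of scaling and of all splits drawn were set before. The split to which the test of scaling was applied was picked after its count of genes was seen. Of 176 groups of 7 libraries examined, 12 (6.82%) held a library set apart from the other 6 by a wide gap, and chance alone picks out about 1 in 20 groups.

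In lens replicate 4, ALDH1A3 was at 0.476 CPM (other lens libraries 1.94 to 2.38), STARD4 at 40.97 CPM (73.6 to 90.6), RPS6 at 89.98 CPM (132.3 to 159.6), ATP5I at 11.7 CPM (18.4 to 23.6) and COX7C at 7.84 CPM (12.9 to 18.2), and its score on the second principal component was -17.7 (-0.281 to 11.6). These are 6 of the 12, in the 1 lens library with W-linked RNA, and STARD4, RPS6, ATP5I and COX7C lie on chromosome Z. In lens replicate 2, RPLP2 was at 21.6 CPM (16.9 to 18.0) and OTX2 at 21.1 CPM (26.4 to 29.6). RPL27A was at 64.9 CPM in lens replicate 6 (87.5 to 105.4), UQCRB at 22.1 CPM in lens replicate 5 (19.4 to 20.4), and ZEB2 at 85.0 CPM in lens replicate 7 (69.2 to 74.1). PDE6H was at 561.8 CPM in control replicate 7 (638.2 to 695.9).

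Z-linked genes were higher in lens retinas by 0.21 (log2) relative to autosomal genes. Among the 9 libraries without W-linked RNA the difference of medians was 0.0141, and the mean level of Z-linked over autosomal genes was 0.151 ± 0.0276 in lens (SD, n = 6) and 0.138 ± 0.038 in control libraries (SD, n = 3). That difference of 0.0132 (SE 0.0247; exact permutation p = 0.56 over 84 assignments) argues against lens wear as the whole cause of the shift. The shift is consistent with the unequal number of libraries with W-linked RNA, 4 control and 1 lens, which the labels do not record as the sex of the birds.

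Clock genes moved in both directions. The adjusted p of the list for change in either direction was 9.16e-06 with the W-linked RNA covariate, which argues against the W-linked RNA imbalance as the whole cause. A lower share of photoreceptors would raise the markers of every other cell type, but 92 such markers lay at -0.0523 relative to all genes (SE 0.0183). That SE is over genes and treats the markers as independent, while their estimated correlation reached 0.228 in the amacrine list. Bipolar markers had a median of -0.03, near that of all genes (-0.04). The markers thus did not rise as a set, but a lower share of photoreceptors stays open. A difference in time of day at collection stays open and cannot be told apart from lens wear, since 0 lines of the labels give a time. Lens wear itself may shift the clock, which is a hypothesis that these data do not separate from collection time.

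The real grouping gave 11 changed genes, and 2 of 100 splits of the 14 libraries, the real one included, gave as many, but the highest other split gave 977, which points to a structure of the samples. That split exchanges control replicate 5 with lens replicate 6, and of 49 such exchanges of 1 library per group it gave the most (next 131; 5 exchanges gave more than 11). Of its 977 genes, 919 were lower and 58 higher in the group labelled lens. It called 401 genes after median ratio rescaling and 233 after quantile normalization. The count fell with rescaling but stayed above 11, which argues against scaling as the whole cause. On an axis fitted to the candidate genes in the other 12 libraries, where control minus lens is 1, control replicate 5 minus lens replicate 6 was -0.109 (spread 0.289), and on an axis fitted to all genes it was -0.649, each the lowest of 49 such pairs (medians 0.698 and 0.463; 2 and 8 pairs below 0). The candidate value lies within its spread of 0, farther than that spread from the median pair and from its mirror, which exchanged labels would give, and the exchange called 3 candidate genes and 2 lists by camera where the real labels gave 5 and 9 (27 against 9 lists by fry), so exchanged labels cannot be told apart from variation between birds, in a pair picked because its exchange calls many genes.

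For the 11 changed genes, the share of 2 in 100 makes chance unlikely over all splits drawn but does not exclude it. Of the 23 drawn splits with the same imbalance of W-linked RNA as the real one, 2 gave as many. The other was the one with 977, so chance stays open there. For genes changed by at least 1.5-fold, the real value was 1, the highest other split gave 47, and 5 of 100 splits gave as many, so chance cannot be excluded. For candidate genes adjusted over the list alone, the real value was 5 and the highest other split gave 3. Thus 1 of 100 splits, the real one, gave as many (1 of 23 with the same imbalance of W-linked RNA). At that share chance is unlikely but not excluded. Among the 49 exchanges of 1 library per group, which keep 12 of the 14 labels, 2 gave as many or more: 7 with control replicate 4 and lens replicate 6 exchanged, and 5 with control replicate 4 and lens replicate 4 exchanged. For gene lists by camera, the real value was 9, the highest other split gave 15, and 7 of 100 splits gave as many, so chance cannot be excluded. By fry the real value was 9, the split with 977 genes gave 27, and the other splits drawn gave 1 at most. Chance is not excluded there either.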

How the results depend on the processing

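The alternatives chosen only after the data were seen were W-linked RNA as a covariate, the libraries without it, the fit without genes on Z and W, rescaling to the same sum and voom on recovered reads; edgeR and DESeq2, planned only if whole reads could be recovered for nearly all values, were not run because they could not. The 11 changed genes became 0 with no filter (18619 genes tested), 0 with quantile normalization, 0 with the exact Wilcoxon test, 21 with arrayWeights, 17 with the code letter as a covariate, 19 with the W-linked RNA covariate and 2 among the 9 libraries without W-linked RNA; the counts by limma at an unadjusted p under 0.05 were 2137 with no filter and 1866 with quantile normalization, and 1442 by Wilcoxon. Other settings gave 8 to 14. By Wilcoxon even genes whose groups do not overlap could not pass (lowest adjusted p = 0.219). Among genes named by the rule, 9 passed, and 0 with no filter, quantile normalization, Wilcoxon or without W-linked RNA libraries. The 1 gene past 1.5-fold became 2 with pseudocount 0.1, arrayWeights, the code letter, voom and the libraries without W-linked RNA, 3 with the W-linked RNA covariate, and 0 with no filter, quantile normalization, robust eBayes, Wilcoxon and without genes on Z and W, which removes RBP4. Candidate genes adjusted over the list alone went from 5 to 1 with Wilcoxon. Lists called went from 9 to 0 with an estimated correlation and to 17 in the libraries without W-linked RNA. The adjusted p of the first component went from 0.0647 to 0.0498 with pseudocount 5. Signs turned for gene GJD2 (0.0182 with median ratio, 0.0039 with quantile normalization, 0.0163 without W-linked RNA libraries, 0.0102 with the same sum), gene NOG (0.0358 with quantile normalization, 0.0735 without W-linked RNA libraries), gene OPN4 (0.0527 with the W-linked RNA covariate, 0.0780 without those libraries), gene ADCYAP1 (0.0219) and gene ALDH1A3 (0.0126), both without W-linked RNA libraries. Apart from the limit of the Wilcoxon test and the removal of RBP4 with the genes on Z, the cause of these differences was not tested. Leaving out each library gave 0 to 18 changed genes, 0 to 4 past 1.5-fold, 0 to 9 named genes, 4 to 7 candidates and 6 to 12 lists, and log2 fold changes of -0.148 to 0.0571 for gene ALDH1A3, -0.0522 to 0.00522 for gene GJD2 and -0.101 to 0.0248 for gene NOG. Across all named genes and alternatives, 2119 values kept sign and side of the threshold, 171 lost the call, 21 gained it and 20 turned sign; for lists these were 360, 30, 15 and 0. Depth limits genes near the floor of 0.0724 to 0.0973 CPM.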

Other observations

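The values of DIO2, DYTN, MDH1B and ETV5 were singled out only after they were seen, and no hypothesis was tested on them. DIO2, the deiodinase that activates thyroid hormone, was at 73.2 ± 17.0 CPM in controls and 49.6 ± 5.76 CPM in lens retinas (SD, n = 7 each; log2 fold change -0.53, adjusted p = 0.0955), and passed only among the 9 libraries without W-linked RNA. DYTN and MDH1B, neighbours on chromosome 7, were at 3.85 ± 2.84 and 2.93 ± 1.77 CPM in controls and at 0.621 ± 0.242 and 0.840 ± 0.253 CPM in lens retinas (log2 fold changes -1.33 and -0.96, adjusted p = 0.116 and 0.12, neither passing). ETV5, a transcription factor induced by growth factor signalling, had a log2 fold change of -0.59 with an adjusted p of 0.0693, and groups that did not overlap; with the W-linked RNA covariate it passed (-0.71, adjusted p = 0.0363).

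Some lists not described above held members that passed adjusted over the list alone, none over all genes, and not all are named here. The receptors of insulin and insulin-like growth factor, INSR (-0.31) and IGF1R (-0.25), fell adjusted over the list alone among 29 neuropeptide receptors, and NPR3, the natriuretic peptide clearance receptor, rose (0.30, but 0.16 with the W-linked RNA covariate and 0.14 among the 9 libraries without W-linked RNA). With the W-linked RNA covariate these 3 calls were lost (adjusted p = 0.057, 0.057 and 0.187 over the list alone), and among the 9 libraries without W-linked RNA 0 receptors passed by limma (4 at an unadjusted p under 0.05). PSMD2 (-0.44) fell among 30 proteasome subunits, GLRA2, a glycine receptor subunit (-0.23), among 30 genes of inhibitory transmission, and PRKG1, the kinase activated by cyclic GMP (-0.33), among 13 genes of nitric oxide signalling. P2RY12, a microglial receptor (-0.25), fell among 17 genes of microglia and leukocytes. With the covariate PSMD2 (0.0176), GLRA2 (0.0116) and PRKG1 (0.00592) still passed over the list alone and P2RY12 (0.104) did not, and among the 9 libraries PRKG1 (0.0142) passed while PSMD2 (0.340), GLRA2 (0.137) and P2RY12 (0.062) did not. Of 46 genes near human refractive error loci, 0 passed by limma over the list alone (11 at an unadjusted p under 0.05), with a median of -0.08, an adjusted p of 0.0896 by camera and 0.0291 by fry. Markers of amacrine cells (median -0.10, adjusted p = 0.164) and of pigment epithelium (-0.11, 0.185) did not pass camera. The direction of camera was up although the median lay below 0 for genes of acetylcholine transmission, cell cycle, the proteasome, the lens crystallins, the interferon response and bipolar cells, none of which passed. For myelin genes (0.03) and for vessels (0.01) the median was above 0 and the mean below.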
